A study of Homo sapiens with 2 samples.

How the data were processed

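RNA of a 22Rv1 line stably transfected with ESE1 and of an empty-vector 22Rv1 line was measured on 2 two-colour Agilent human 4x44K arrays, dye-swapped. Per the file headers, the slides were scanned and quantified with Agilent Feature Extraction 9.5.3.1, and both arrays lie on 1 slide. The submitters' processing notes name Feature Extraction and limma, and their settings are not given in the sources used here. The deposited scanner files hold, per spot, the mean signal intensity and the median local background intensity of each channel, which are not normalized. Per the file headers, they also hold processed intensity values, background-subtracted, detrended and dye-normalized by Feature Extraction, and the log10 ratio of Cy5 over Cy3. That log10 ratio equalled the log10 of the processed Cy5 over Cy3 intensity within 0.001 for 100% of the spots whose processed signals had not been replaced by a surrogate. The deposited value table of the whole series gives log2 ratios by the authors for 41093 probes. Set against the scanner values, its columns ran as Cy5 over Cy3 without the swap being turned (correlation with the scanner software's log2 ratio 0.96 and 0.97, correlation of the columns -0.62). Its medians were 0.069 and 0.026, with 249 and 219 missing values. Its slope was 0.78 and 0.82 on the scanner software's ratios and 1.17 and 1.16 on the ratios computed here, so that its background correction and centring stay unknown. It was used only as an alternative.

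The mean signals were background-corrected with normexp at an offset of 50 on all spots and normalized within arrays by loess, with control spots and spots flagged as outliers (120 and 196 spots) given no weight and left out afterwards. Saturated spots were to be kept, and there were 0. Spots of the same probe were averaged. Ratios were turned to ESE1 line over empty-vector line on both arrays, with the direction taken from the dyes in the labels. The offset shrinks ratios of dim probes towards 0. Of 41000 probes, 29872 were kept, those well above background in the channels of the ESE1 line on both arrays or in those of the empty-vector line on both arrays. Array annotation dates from the array design. Of the 41000 probes, 23958 were named through their accession in a table of RefSeq genes of GRCh38.p14, 2755 through a symbol, 1032 through a synonym held by a single gene, and 13255 kept the name in the file. Coordinates are those of the array files (NCBI36/hg18). Each gene was represented by its kept probe of highest mean intensity, and probes with no gene name stood for themselves, which left 21831 features, 14064 of them with a gene symbol of the reference.

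Ratios were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without trend or robust settings, and with Benjamini-Hochberg adjustment over all features at a threshold of 0.05. The fit had 1 residual degree of freedom per gene, 14.2 prior degrees of freedom and a prior SD of 0.155. Features were also counted by size alone, with a log2 ratio of at least 1 on each array. Gene lists, 41 in all, were fixed before the data were examined, as were the tests and the rule for named genes. The 40 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand the same test with an estimated correlation and the place of each list's median among 10000 random lists of equal size matched on mean intensity in 20 bins. With an estimated correlation, the smallest adjusted p of any list was 0.66. That test has 1 residual degree of freedom and little power, and even the cholesterol synthesis list had an unadjusted p of 0.057 in it. Its adjusted p of 0.66 therefore cannot decide whether a list was shifted. Named genes were ELF3, the ETS members past the test and the closest relatives of ELF3, the 15 largest mean log2 ratios in each direction among called genes with the same sign on both arrays and a gene symbol (names of unnamed loci, open reading frames and antisense transcripts left out), up to 4 called members of largest ratio per list, and up to 2 members of the central lists that did not pass. A gene not well above background in the channels of a line on both arrays has only a bound there. Its fold was computed from channel values after loess and Aquantile, with the dim line at the higher of its own value and the lowest signal well above background.

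The test was checked on simulated arrays for the comparison of the ESE1 line with the empty-vector line. With 21831 features and the estimated spread, 200 were changed by known folds, 50 at each size. It recovered 10% of those changed 1.25-fold, 78% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and it called 10 of 21631 unchanged features. Camera called a list shifted by -0.5 and 0 of 39 unshifted lists. The simulated features were independent of each other, had the spread that the test assumes and carried no dye effect. The check therefore cannot show how the tests behave under correlation between genes, dye effects or shared RNA extracts. It also gave only 154 calls, while 4036 higher and 3085 lower features were called in the data. The adjustment was therefore stricter in the simulation, and its shares recovered and its false calls do not carry over to the data.

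Alternatives were other background corrections (offset 10, no subtraction, the scanner software's processed ratios), median centring, Aquantile normalization, the authors' value table, other filters on dim probes, trend and robust settings of eBayes, the mean of a gene's probes, all probes as features, other thresholds, other list tests and each array alone. Because both arrays lay on 1 slide, slide was not fitted as a block. No column of other samples was used.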

Results

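Gene expression was compared between 2 stable derivatives of 22Rv1, an established human prostate carcinoma cell line. The ESE1 line carried an expression construct for ESE1, the epithelium-specific ETS transcription factor encoded by ELF3. The control line carried the empty pcDNA3.1 vector, and both were kept under G418 selection at 700 ug per ml. RNA of both lines was hybridised together on 2 two-colour Agilent oligonucleotide arrays with the dyes swapped, so that the ESE1 line was read in Cy5 on array 1 and in Cy3 on array 2. Each array held 45015 spots, of which 1639 were controls. On array 1, the median spot signal was 341 in the channel of the ESE1 line and 168 in the channel of the empty-vector line, over median local backgrounds of 50 and 49.5. On array 2 these signals were 238 and 321, over backgrounds of 48 and 50. Between 69.9% and 77.0% of the spots were well above background, depending on array and channel, and no spot was saturated. Across the 21831 features tested, the log2 ratios of the ESE1 line over the empty-vector line correlated between the arrays with r = 0.84 (across genes, which are not independent replicates). The labels do not say whether the arrays held separate RNA extracts. The p-values of genes therefore rest only on the spread between 2 arrays, which may be technical. Those of gene lists at the preset correlation rest on the spread across genes, which are treated as nearly independent. Each comparison is of a single ESE1 line with a single control line. With 1 residual and 14.2 prior degrees of freedom, the spread behind each gene's p-value came mostly from all features together. The number of arrays limits the precision of every value, and errors below are SDs over 2 arrays.

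The first question was whether the transfected gene was higher in the line labelled as carrying it. ELF3 was 5.09-fold higher in the ESE1 line, with a log2 ratio of 2.35 ± 0.21 (SD, n = 2; limma adjusted p = 5.7e-10), and it was well above background in both lines on both arrays. The only ELF3 probe lies at position 200251052 to 200251111 of chromosome 1 (NCBI36/hg18) and is assigned to NM_004433. Whether it lies in the coding part or in the 3' untranslated part of the transcript was not established here, so the value is the summed signal of any vector-borne and endogenous ELF3 transcript that the probe reads. Among the 22 measured members of the ETS family of transcription factors, 6 were higher and 0 lower (the same adjusted over the list alone), and 16 did not pass the test. Those higher were ELF3, ETV5 (log2 ratio 1.16 ± 0.04), FEV (0.75 ± 0.15), ETS2 (0.70 ± 0.16), ETV1 (0.65 ± 0.05, or 0.33 by a second probe) and ELF5 (0.51 ± 0.13). The other epithelial ETS factors had log2 ratios of -0.23 ± 0.22 for EHF (adjusted p = 0.13) and -0.09 ± 0.12 for SPDEF (adjusted p = 0.59). The family as a list was not shifted by limma's camera test with a preset inter-gene correlation (median log2 ratio 0.08, adjusted p = 0.081). Its median was 0.11 on array 1 and 0.03 on array 2. ELF3 itself counts in that test, and the family was not tested without it.

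The lines differed widely. At an adjusted p below 0.05, 4036 features were higher and 3085 were lower in the ESE1 line, while 9107 had an unadjusted p below 0.05. The median absolute log2 ratio of the called features was only 0.47. By size alone, 358 features were at least 2-fold higher on both arrays and 136 at least 2-fold lower, and all 494 of them passed the test. At least 4-fold on both arrays, there were 40 higher and 27 lower. The counts by test depended on the normalization: with median centring in place of loess, 531 features were called higher and 180 lower, which raised the share of higher calls from 56.7% to 74.7%. The counts of features at least 2-fold on both arrays were then 281 higher and 104 lower.

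**Figure D1:**
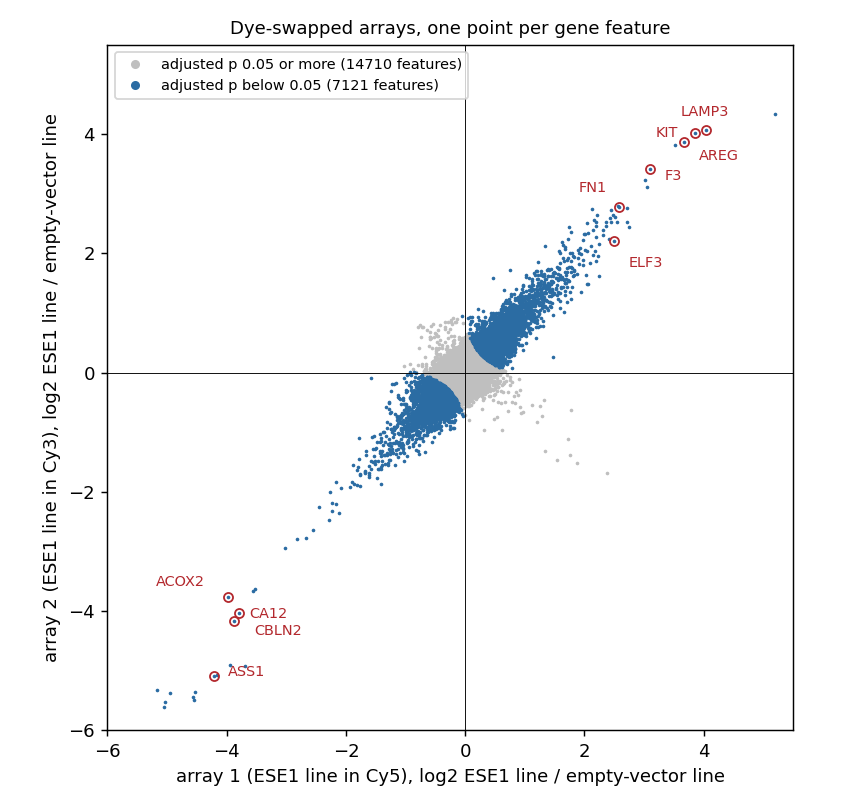
Log2 ratio of the ESE1 line over the empty-vector line on array 1 (horizontal axis) and on array 2 (vertical axis), 1 point per feature, with dark points for the features at an adjusted p below 0.05 and circles around 10 named genes. The circled genes lie near the diagonal, from ASS1 at a mean of -4.66 to LAMP3 at a mean of 4.05, and ELF3 lies at 2.50 on array 1 and 2.20 on array 2.

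LAMP3, which encodes a lysosome-associated membrane protein, was 16.6-fold higher in the ESE1 line, the largest ratio among named genes (log2 ratio 4.05 ± 0.02; adjusted p = 6.7e-13). KIT, the receptor tyrosine kinase for stem cell factor, was 15.3-fold higher (3.94 ± 0.11). AREG, which encodes the EGF receptor ligand amphiregulin, was 13.7-fold higher (3.77 ± 0.14), and the peptide hormone gene SPX was 12.7-fold higher (3.66 ± 0.21). F3 (tissue factor, the initiator of blood coagulation) was 9.58-fold higher, SH3BGR 8.71-fold, and EPAS1 (the hypoxia-inducible factor subunit HIF-2α) 8.48-fold. FN1 (fibronectin) had a log2 ratio of 2.68 ± 0.15. The others among the 15 largest were TCL1B, MAEL, S100P, GDF15, FIBIN, A2M and CEMIP, with log2 ratios from 2.54 (CEMIP) to 2.74 (TCL1B). Each of these 15 genes was well above background in both lines. A second EPAS1 probe read a smaller log2 ratio of 1.29.

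Among named genes lower in the ESE1 line, ASS1 had the largest ratio, and several probes without a gene symbol went lower still. Among those were probes that the array also annotates as argininosuccinate synthase (log2 ratios -5.29 and -5.25). ASS1, the gene of argininosuccinate synthase, which makes the precursor of arginine, was 25.2-fold lower (log2 ratio -4.66 ± 0.62, limma adjusted p = 6.4e-12). CA12 (carbonic anhydrase XII) was 16.2-fold lower (-4.02 ± 0.21), CBLN2 15.1-fold (-3.91 ± 0.18) and ACOX2, a peroxisomal oxidase of branched-chain fatty acids and bile acid intermediates, 14.7-fold (-3.87 ± 0.15). FAM107A had a log2 ratio of -3.62 ± 0.07. SMOC1 was 6.62-fold lower, UGT8 4.72-fold, the ephrin receptor gene EPHA3 4.62-fold and CHD9 4.55-fold. The retinaldehyde dehydrogenase genes ALDH1A1 and ALDH1A3 had log2 ratios of -2.14 ± 0.19 and -1.87, and the growth factor gene IGF1 was 3.60-fold lower. YPEL2, HMGCS1 and INSIG1 completed the 15 genes, the latter 2 with log2 ratios of -2.01 and -1.93. FAM107A and ALDH1A3 were well above background in the ESE1 line on only 1 of 2 arrays, and the others in both lines on both arrays. The sizes of these 2 ratios are therefore uncertain, and they ranged from -6.54 to -2.24 (FAM107A) and from -4.09 to -1.82 (ALDH1A3) over the processing settings. Probes of the same gene disagreed in size for several of them. The 2 SMOC1 probes read -2.73 and -1.21, and the 4 kept CHD9 probes ranged from -2.19 to -0.03, the 4 CA12 probes from -4.02 to -0.92 and the 3 FAM107A probes from -3.62 to -0.86, the brightest probe being the one reported. The probes of YPEL2 reached up to -0.66 and those of IGF1 up to -1.07. Over all called genes with more than 1 kept probe, 181 of 2139 had a probe of opposite sign.

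**Figure D2:**
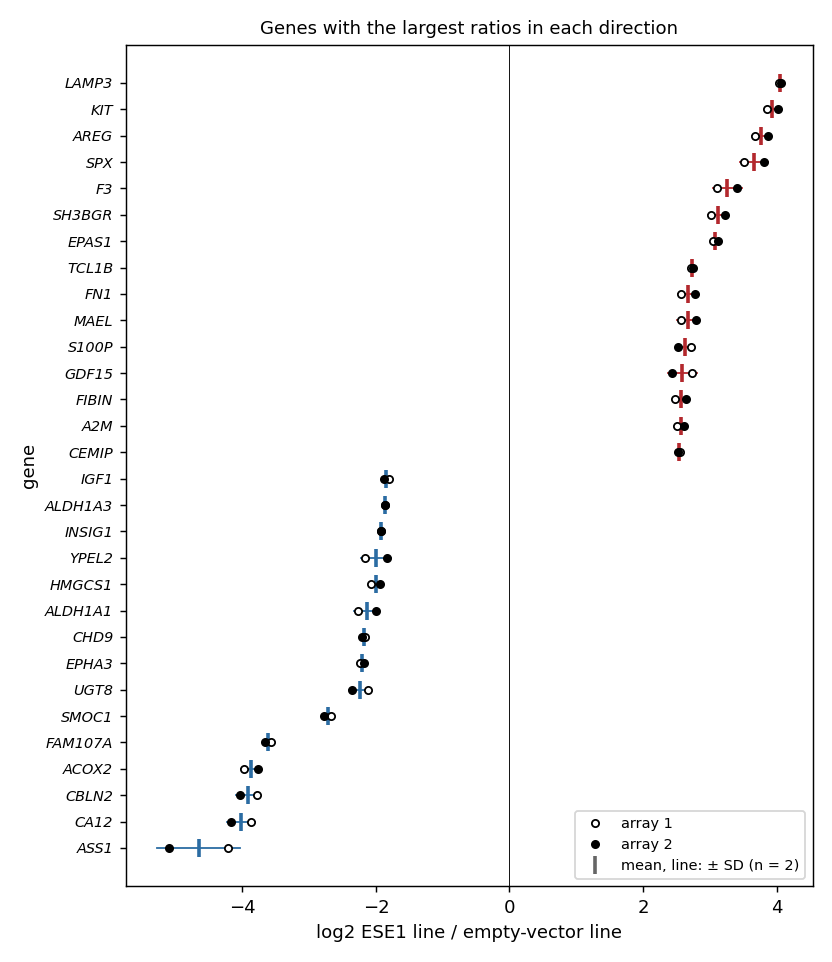
Log2 ratio of the ESE1 line over the empty-vector line (horizontal axis) for the 15 genes with the largest positive and the 15 with the largest negative mean, with open circles for array 1, filled circles for array 2, a tick for the mean and a line for ± SD (n = 2). Both arrays lie on the same side of 0 for every gene shown, which the rule for choosing them required, and the widest spread is that of ASS1 (SD 0.62).

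ESE1 has been studied as a regulator of NF-κB signalling and inflammatory genes, so these groups were a main question of the comparison. NF-κB target genes as a list were not shifted. Of 28 measured members, 3 were higher, 3 lower and 22 not past the test (2 higher and 2 lower adjusted over the list alone). The median log2 ratio was 0.08, at 0.12 on array 1 and 0.03 on array 2, and the camera adjusted p was 0.65. PTGS2 (cyclooxygenase-2) was 1.14 ± 0.19 higher on the log2 scale and CFLAR 0.34 ± 0.10, whereas SDC4 (-1.06 ± 0.34) and SOD2 (-0.39 ± 0.02) were lower. NFKBIA, the IκBα gene and a direct NF-κB target, had a log2 ratio of 0.09 ± 0.05 (adjusted p = 0.57), and ICAM1 had 0.06 ± 0.01 (adjusted p = 0.71). Of 28 NF-κB pathway components, 4 were higher (TRAF5 at 0.69, TLR3 at 0.56 and TAB2 at 0.34 among them), 1 was lower (NFKB2 at -0.30) and 23 did not pass (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.94). Their median log2 ratio was -0.01, at 0.07 on array 1 and -0.08 on array 2, and their mean was 0.03. The calls of CFLAR and TAB2 were lost with the scanner software's log ratios, with the authors' value table and with median centring. Only 12 of 41 cytokine and chemokine genes were measured. Of these, 4 were higher, with IL15 at 0.97 ± 0.31 and TNFSF15 at 0.78 ± 0.17. A further 2 were lower, CX3CL1 at -0.62 ± 0.11 and CXCL5 at -0.36 ± 0.22, and 6 did not pass (4 and 2 adjusted over the list alone). The median log2 ratio of the list was 0.21, at 0.17 on array 1 and 0.13 on array 2 (camera adjusted p = 0.50). It was 0.010 with no filter on dim probes and 0.0048 when both lines had to be well above background. The other CX3CL1 probes reached -0.22.

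Genes named in earlier work as ESE1 targets were shifted upwards as a list. Of 12 measured members out of 25, 7 were higher, 0 lower and 5 not past the test (7 higher and 1 lower adjusted over the list alone), with a median log2 ratio of 0.33 and a camera adjusted p of 0.017, or adjusted p = 0.66 with an estimated correlation. The median was 0.038 with no filter on dim probes (adjusted p = 0.045) and 0.22 when both lines had to be well above background (adjusted p = 0.046). The tight-junction gene CLDN7 was 2.82-fold higher, and PTGS2, TFF3 (1.01 ± 0.23) and IL23A (0.66 ± 0.19) were also higher, while the value for the matrix protease gene MMP9 was 0.13 ± 0.12 (adjusted p = 0.39). TFF3 was well above background in the empty-vector line on only 1 of 2 arrays.

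Both epithelial and mesenchymal genes had members that rose, and neither list was shifted as a whole. Of 39 epithelial markers, 14 were higher, 3 lower and 22 not past the test (15 higher and 4 lower adjusted over the list alone; median log2 ratio 0.09; camera adjusted p = 0.081). The median was 0.23 on array 1 and -0.04 on array 2. Besides ELF3 and CLDN7, the splicing regulator gene ESRP1 (1.40 ± 0.08) and the desmosomal cadherin gene DSC2 (1.03 ± 0.07) were among those higher, and EPCAM had a log2 ratio of 0.05 ± 0.20 (adjusted p = 0.77). Of 24 measured mesenchymal genes, 8 were higher, 0 lower and 16 not past (8 and 0 adjusted over the list alone; median 0.05, at 0.13 on array 1 and 0.02 on array 2; camera adjusted p = 0.069). FN1 led them, followed by ITGA5 (0.89 ± 0.01), DCN (0.58 ± 0.01) and COL3A1 (0.45 ± 0.05). TWIST1 and SNAI1, transcription factors that drive the mesenchymal state, had log2 ratios of 0.01 ± 0.04 (adjusted p = 0.95; a second probe read -0.31) and -0.11 ± 0.13 (adjusted p = 0.50). COL3A1 and SNAI1 were well above background in the empty-vector line on only 1 of 2 arrays. The epithelial list passed the camera threshold with no filter on dim probes (adjusted p = 0.025) and with median centring (0.020). The mesenchymal list did so with a background offset of 10 (0.044), with the value table (0.047) and with the stricter filter (0.049). The epithelial list holds ELF3, the transfected gene, and was not tested without it.

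Extracellular matrix, TGF-β and growth factor feedback genes were shifted upwards. Of 34 extracellular matrix and basement membrane genes, 13 were higher and 3 lower (15 and 3 adjusted over the list alone), 18 did not pass, the median log2 ratio was 0.17 and the camera adjusted p was 0.013, or adjusted p = 0.66 with an estimated correlation. After FN1, the largest ratios were those of COL12A1 (2.20 ± 0.21), SPOCK1 (1.89 ± 0.12) and THBS1 (1.78 ± 0.03), and a second COL12A1 probe read 1.04. Of 28 TGF-β and SMAD targets, 12 were higher, 2 lower and 14 not past (13 and 2 adjusted over the list alone; median 0.16, at 0.10 on array 1 and 0.24 on array 2; adjusted p = 0.044, or adjusted p = 0.66 with an estimated correlation). That call was lost with camera on ranks (0.12), the scanner software's log ratios (0.090) and matched random lists (0.068). INHBA, which encodes the activin A subunit, was 5.10-fold higher (2.35 ± 0.06) and ID1 3.01-fold (1.59 ± 0.13), whereas CCN2, also a target of YAP and TEAD, was 2.81-fold lower (-1.49 ± 0.24). Of 32 feedback genes of EGFR and MAPK signalling, 15 were higher, 4 lower and 13 not past (16 and 4 adjusted over the list alone; median 0.25, at 0.38 on array 1 and 0.19 on array 2; adjusted p = 0.00056, or adjusted p = 0.66 with an estimated correlation). AREG led them, followed by the pathway inhibitors SPRY4 (2.41 ± 0.06), DUSP10 (2.01 ± 0.12) and DUSP1 (1.70 ± 0.02). Of 12 measured fibroblast and stroma markers, 6 were higher, 0 lower and 6 not past (7 and 0 adjusted over the list alone; median 0.36, or 0.087 with no filter on dim probes; adjusted p = 0.020, or adjusted p = 0.66 with an estimated correlation and 0.070 on ranks), with PDGFRA at 2.10 ± 0.17 and COL5A2 at 1.66 ± 0.05, whose 3 probes ranged from 0.62 to 1.66.

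**Figure D3:**
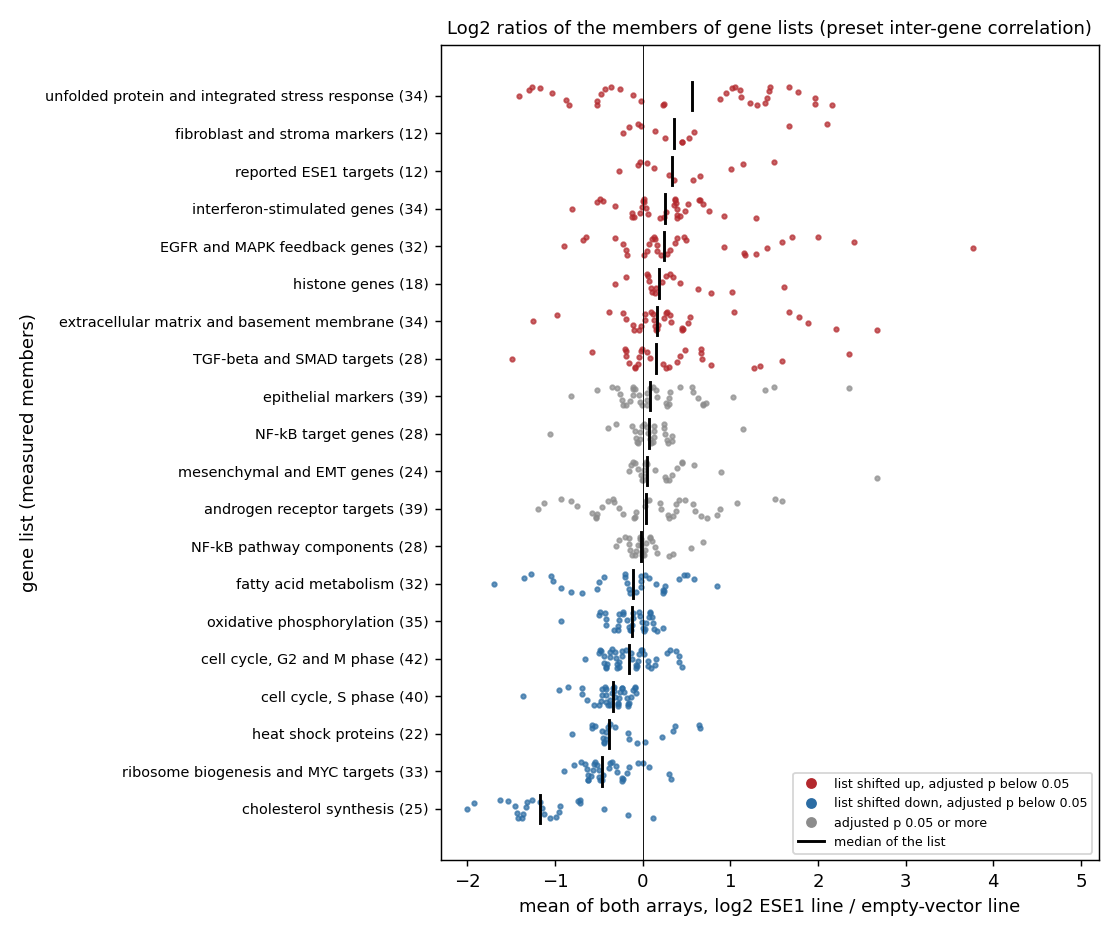
Mean log2 ratio of the ESE1 line over the empty-vector line (horizontal axis) for each measured member of 20 gene lists (rows, with the number of measured members), with a black bar at each list's median and colour for the camera call at the preset correlation of 0.01. The cholesterol synthesis list lies farthest from 0, at a median of -1.17, and the members of the stress response list lie in separate groups above and below 0.

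Genes of cholesterol synthesis and uptake fell almost without exception. Of 25 members, 23 were lower, 0 higher and 2 not past the test, with the same counts adjusted over the list alone. The median log2 ratio was -1.17, at -1.19 on array 1 and -1.17 on array 2, and the camera adjusted p was 5.1e-22, or adjusted p = 0.66 with an estimated correlation. HMGCS1, which encodes the enzyme that makes HMG-CoA, was 4.02-fold lower (-2.01 ± 0.10) and INSIG1, a sterol-regulated gene of the endoplasmic reticulum, 3.80-fold lower. LSS, the lanosterol synthase gene, had a log2 ratio of -1.53 ± 0.07, and its 4 probes ranged from -1.53 to -0.91. None of 10000 random lists matched on intensity had as low a median. Of 32 fatty acid metabolism genes, 11 were lower, 5 higher and 16 not past (the same adjusted over the list alone; median -0.11; adjusted p = 0.036, or adjusted p = 0.66 with an estimated correlation). ACADL (-1.69 ± 0.15), SREBF1, which encodes a lipogenic transcription factor (-1.35 ± 0.06), SCD (-1.28 ± 0.08) and LPL (-1.04 ± 0.17) were the lowest. On array 2 alone, the median of the fatty acid list was 0.01, and its call was lost with camera on ranks (adjusted p = 0.17) and matched random lists (0.11). The 3 SCD probes ranged from -2.10 to -1.28.

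Stress genes moved in opposite directions. Of the 34 members of the unfolded protein and integrated stress response list, 17 were higher, 12 lower and 5 not past the test (18 and 12 adjusted over the list alone). The median log2 ratio was 0.56 and the camera adjusted p was 0.044, or adjusted p = 0.66 with an estimated correlation. That call was lost with camera on ranks (0.26) and with the scanner software's log ratios (0.088). Those with the largest ratios were SLC7A11, a cystine transporter gene (2.16 ± 0.24), ASNS, the asparagine synthetase gene (1.97 ± 0.11), ATF3 (1.96 ± 0.18) and TRIB3 (1.77 ± 0.15). A second ASNS probe read 0.16, and the 3 SLC7A11 probes ranged from 1.20 to 2.16. Chosen after their values were seen, the endoplasmic reticulum chaperone genes HSPA5 (-1.30 ± 0.10) and PDIA4 (-1.41 ± 0.19) were lower. Of 22 heat shock protein genes, 13 were lower, 4 higher and 5 not past (the same adjusted over the list alone; median -0.39; camera adjusted p = 0.020, or adjusted p = 0.66 with an estimated correlation). HSPH1 (-0.81 ± 0.01) and HSPA4L (-0.58 ± 0.24) were lower, and HSPB8 (0.65 ± 0.09) and HSPA9 (0.64 ± 0.15) were higher. Among 35 NRF2 and oxidative stress genes, 14 were higher and 8 lower (15 and 9 adjusted over the list alone; median 0.14; adjusted p = 0.15), with AKR1C3 at 2.24 ± 0.05 and ABCC2 at -1.25 ± 0.23.

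Genes of DNA replication and ribosome production were lower. Of 40 S phase genes, 23 were lower, 0 higher and 17 not past (27 lower adjusted over the list alone), with a median log2 ratio of -0.34 and a camera adjusted p of 1.2e-09, or adjusted p = 0.66 with an estimated correlation. UHRF1 (-1.37 ± 0.03), RFC3 (-0.95 ± 0.08), MCM10 (-0.85 ± 0.11) and CDC45 (-0.69 ± 0.01) were the lowest. Of 42 genes of G2 and M phase, 16 were lower, 5 higher and 21 not past (18 and 6 adjusted over the list alone; median -0.16, at -0.17 on array 1 and -0.24 on array 2; adjusted p = 0.020, or adjusted p = 0.66 with an estimated correlation and 0.077 with median centring). Of 33 ribosome biogenesis genes and MYC targets, 23 were lower, 2 higher and 8 not past (the same adjusted over the list alone; median -0.46; adjusted p = 2.7e-08, or adjusted p = 0.66 with an estimated correlation). MYC itself was at -0.89 ± 0.12, with its 3 probes between -1.05 and -0.11, LYAR at -0.79 ± 0.23 and RRS1 at -0.71 ± 0.06. Of 35 oxidative phosphorylation genes, 8 were lower, 0 higher and 27 not past (6 and 0 adjusted over the list alone; median -0.12, at -0.19 on array 1 and -0.08 on array 2; adjusted p = 0.029, or adjusted p = 0.66 with an estimated correlation, 0.074 with the scanner software's log ratios, 0.068 against matched random lists and 0.054 with the eBayes trend), with ATP5MC1 at -0.93 ± 0.24. Of 18 histone genes, 7 were higher, 0 lower and 11 not past (the same adjusted over the list alone; median 0.18; adjusted p = 0.020, or adjusted p = 0.66 with an estimated correlation and 0.11 against matched random lists).

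Androgen receptor targets moved both ways and the list was not shifted (camera adjusted p = 0.94). Its median log2 ratio was 0.04, at 0.01 on array 1 and 0.06 on array 2. Of 39 measured members, 14 were higher, 13 lower and 12 not past the test (16 and 14 adjusted over the list alone). PTGER4 (1.58 ± 0.11) and FOLH1, which encodes prostate-specific membrane antigen (1.51 ± 0.16), were higher. SORD, the sorbitol dehydrogenase gene (-1.19 ± 0.11), was lower. The markers KLK4 and SLC45A3 had log2 ratios of -0.23 ± 0.21 (adjusted p = 0.14) and 0.29 ± 0.09 (adjusted p = 0.053). Of 22 UGT and steroid metabolism genes, 8 were higher and 4 lower (9 and 5 adjusted over the list alone; median 0.11; adjusted p = 0.25). HSD17B2, which encodes an enzyme that inactivates testosterone and oestradiol, was not well above background in the empty-vector line on either array and was at least 2.06-fold higher in the ESE1 line (adjusted p = 1.6e-06). Such a bound sets the ESE1 line's mean against the lowest signal well above background. Of 18 prostate basal markers, 6 were higher and 1 lower (7 and 2 adjusted over the list alone; median 0.20; adjusted p = 0.12), with ANXA1 at 1.10 ± 0.19 and LAMA3 at -1.25 ± 0.03, or -0.71 by a second probe. Of 25 neuroendocrine markers, 7 were higher and 5 lower (8 and 5 adjusted over the list alone; median 0.05, at 0.08 on array 1 and -0.06 on array 2; adjusted p = 0.68), with the calcitonin gene CALCA at 2.10 ± 0.19 and CHGA at 1.09 ± 0.26. Of 22 stem and progenitor markers, 6 were higher, KIT and KLF4 (1.30 ± 0.03) among them, and 10 lower (6 and 12 adjusted over the list alone). Their median was -0.29 (camera adjusted p = 0.17). Of the random lists matched on intensity, 0.02% had a median as low as the stem and progenitor markers. For the prostate basal markers, 0.57% had one as high.

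Interferon-stimulated genes were shifted upwards at the threshold. Of 34 members, 16 were higher, 5 lower and 13 not past the test (17 and 5 adjusted over the list alone), with a median log2 ratio of 0.26 and a camera adjusted p of 0.044. With an estimated correlation the adjusted p was 0.66, and the call was lost with 5 other settings, such as the mean of a gene's probes (adjusted p = 0.080). ISG20 (1.29 ± 0.16), DDX60 (0.92 ± 0.14) and IFIT2 (0.76 ± 0.15) were higher and IFITM2 (-0.80 ± 0.40) was lower, and a second IFIT2 probe read 0.31. Antigen presentation genes had 11 members higher and 3 lower of 23 (12 and 3 adjusted over the list alone; median 0.27; adjusted p = 0.052), with HLA-F at 0.73, HLA-C at 0.65 and HLA-DMB at 0.65, but second probes of HLA-F and HLA-DMB read 0.28 and 0.21. The lists of p53 targets (adjusted p = 0.21), apoptosis regulators (0.15), matrix proteases (0.11), integrins and adhesion molecules (0.11), keratinization (0.64), WNT targets (0.79), YAP and TEAD targets (0.50), Notch pathway (0.65), hypoxia and glycolysis (0.63), cancer-testis antigens (0.53), HOX genes (0.68) and leukocyte markers (0.22) were not shifted. Of 15 endothelial markers, 2 were measured, which is below the minimum for the test. Within these lists, BTG1 (1.90 ± 0.02), DDIT4 (1.93 ± 0.45), IGFBP3 (1.64 ± 0.15), CDH6 (1.57), KRT10 (1.28 ± 0.10), TNFRSF10B (1.23 ± 0.10) and HOXA13 (1.15) were higher and HOXA6 (-1.36 ± 0.27) was lower.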

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

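ELF3 stayed higher in the ESE1 line under all 11 alternatives with a test (log2 ratio 2.35 to 2.38, adjusted p from 2.5e-14 to 0.00021) and at 2.20 to 2.50 on each array alone. The counts of 4036 higher and 3085 lower features moved by over 1.5 times only with median centring (531 and 180, all of them among the main calls) and when a 2-fold size was required as well (450 and 174). Median centring leaves the intensity-dependent dye effect in the ratios: the correlation between arrays fell from 0.84 to 0.51. The counts at least 2-fold on both arrays (358 and 136) rose to 833 and 351 with the scanner software's processed ratios and to 573 and 220 with the authors' value table; the cause was not tested. Lowering only the offset from 50 to 10 gave 530 and 203. On 1 array alone they were 435 to 509 higher and 195 to 206 lower, since a single array has to pass. Between 11 and 17 lists were called under the other settings, against 15, and 0 with an estimated correlation, which rests on 1 residual degree of freedom and can hardly call any list. The rule for named genes chose 168 genes besides ELF3, called ones and ETS members, not all of them mentioned here. Of these 168 genes, 67 lost their call under median centring, a few of them under another setting as well. The other 101 kept it, or stayed uncalled, under every tested setting in which they were measured, and 0 of the 168 changed sign. Dim genes among the 101, such as FAM107A, ALDH1A3, HSD17B2 and TFF3, had no value when both lines had to be well above background. Genes mentioned outside that rule, such as GLI1, PTCH1, PCK2, HSPA5 and PRDM12, were not put through the settings. Of the uncalled members named from lists other than the ETS family, EPCAM and TWIST1 had opposite signs on the arrays. The NF-κB pathway component list, not called at any setting, changed camera direction with median centring (median log2 ratio 0.041), with no filter (-0.010) and with the stricter filter (-0.014). The androgen receptor target list, not called either, did so with an offset of 10 (median 0.034), the value table (0.036) and the eBayes trend (0.038). The median of the fatty acid list ranged from -0.17 to 0.0092 on single arrays. Besides the estimated correlation, at least 1 setting took away the calls of the interferon, TGF-β, fatty acid, stress response, oxidative phosphorylation, histone, fibroblast and G2 and M phase lists, and none took away the other 7. Camera has no trend or robust setting, so those fits were tested through the z-scores of their statistics. Slide as a block was not run because both arrays were on 1 slide, and counts of tested features have no value on 1 array, where no residual is left. Signal over background limits the dim genes: of the called features, 144 were not well above background in the empty-vector line and 30 not in the ESE1 line on either array.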

Other observations

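The lists of amino acid response genes, endoplasmic reticulum chaperones and Hedgehog genes below were written after the ratios had been seen, as were the tests of dye bias and of a faulty ASS1 probe, and the genes of these lists were chosen after their values were seen, so that the counts and medians of these lists describe the choice and no test of them is given. Of 38 amino acid response genes, which cells raise when amino acids are short, 37 were higher in the ESE1 line, 0 lower and 1 not past the test. Their median log2 ratio was 1.12. They included the serine synthesis genes PHGDH (1.31 ± 0.17), PSAT1 (1.41 ± 0.07) and PSPH (1.13 ± 0.05; lowest of 3 probes -0.03), the aminoacyl-tRNA synthetase genes SARS1 (1.34) and AARS1 (0.95 ± 0.05), the transcription factor genes ATF4 (1.02 ± 0.14) and DDIT3 (1.67 ± 0.12), and PCK2, 5.45-fold higher. Of 21 chaperone genes of the endoplasmic reticulum, 14 were lower, 0 higher and 7 not past (median -0.43), with HSP90B1 at -1.03 ± 0.05 and MANF at -1.18. These lists share members with the stress response list of the report and split its 2 directions.

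Among 16 measured Hedgehog pathway genes, GLI1 was 5.60-fold higher (log2 ratio 2.49 ± 0.04) and PTCH1 5.01-fold (2.33 ± 0.11). Both are known as direct targets of the pathway. In all, 7 were higher, 2 lower and 7 not past, with GLI3 at -0.40 ± 0.23.

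Genes of cholesterol synthesis were lower in the ESE1 line, at a median log2 ratio of -1.17. An error of the intensity-dependent normalization would give like medians to random lists of the same intensity, and 0% of 10000 such lists reached it. Dye bias would turn the sign between the arrays, and 92% of the members lay below 0 on both. Unlike the check on intensity, that on dye bias was written after the ratios had been seen. A difference in culture state between the lines, such as density or the supply of serum lipids, stays open beside an effect of ESE1, because a single line of each kind was compared and neither was tested.

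ASS1 was lower with a log2 ratio of -4.66. A faulty probe would leave other probes of argininosuccinate synthase in place, but the highest of the 4 others stood at -3.58. These others are annotated to further transcripts and pseudogene loci of this family, so probes that read each other's targets may all report the same loss. Loss of the chromosome 9 segment would lower its neighbours, and the median of the 50 named genes measured within 2 Mb was -0.094, with ASS1 and PRDM12 left out. PRDM12, known to be lower before the test was written, had a log2 ratio of -1.52 ± 0.14, and FUBP3, which lies between it and ASS1, had -0.09 and did not pass the test; a loss confined to ASS1, effects of ESE1 and clonal selection were not tested.

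Genes next to each other shared their direction more than chance orders gave. Over 13459 neighbouring pairs on the autosomes, the only chromosomes examined, the Spearman correlation of log2 ratios was 0.096, above the highest of 1000 orders shuffled within chromosomes (0.035), yet no autosome had a median beyond 0.077 in size, so gains or losses of whole autosomes are not apparent and smaller segments cannot be told apart from co-regulated clusters. Among autosomal windows of 21 genes, only some on chromosomes 5 and 19 had medians beyond those of 100 shuffled orders. On chromosome 5, 14 of 15 β-protocadherin genes and pseudogenes were higher (median log2 ratio 0.99), against 5 of 10 γ- and 0 of 5 α-protocadherin genes. The pseudogenes PCDHB17P (1.20) and PCDHB18P (1.09) were among the 14. TAF7, which lies among the protocadherin genes, was at 0.70 ± 0.03. A gain reaching well beyond these clusters would raise their neighbours, whose median within 3 Mb on both sides was 0.072 over 56 genes. That median cannot speak on a gain confined to the clusters, which could also raise TAF7 and was not tested. Probes of near-identical protocadherins or zinc finger genes (chromosome 19) that read each other's transcripts were not tested either.

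Among the 15 genes of largest ratio in each direction, the probes of ACOX2 and FAM107A, both lower, start 59.0 kb apart on chromosome 3. PDGFRA is not among these genes and was added to the search by choice. Its probe starts 443 kb from that of KIT on chromosome 4, and both genes were higher. How often such pairs arise by chance was not tested.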
